A study of Mus musculus with 2 samples.

How the data were processed

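Droplet-based single-cell RNA sequencing with 10x 5' v1.1 chemistry, per the labels' protocols, gave 1 library of digested EMT6 mouse tumour tissue for each of 2 groups, Luc and PDE6G. The deposited values are raw UMI counts per gene and barcode, with 1 matrix per library and no normalization. Per the file headers the matrices come from Cell Ranger 9.0.1, whereas the submitters' processing notes name Cell Ranger 2.1.1 and the genome build mm10; which version made the counts is not settled here. The aligner settings and the annotation release are not given in the sources used here. Groups were taken from the sample titles. Of the 55357 gene IDs, 52081 matched GENCODE vM21 on GRCm38, which was used for coordinates only.

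Cells with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept, which removed 16 Luc barcodes and 0 PDE6G barcodes. Scrublet, run per library, called 930 Luc (6.01%) and 354 PDE6G (3.20%) cells as doublets, and these were removed. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within each library, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 1 on both libraries together, giving 24 clusters. The main settings, gene lists, marker lists and the rule for named genes were fixed before the data were examined.

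A cluster took the class whose markers scored highest if at least 3 markers were each detected in 10% or more of its cells. It stayed without a name if its 10 leading genes held more markers of another class, or if its median UMI count was low and no own marker was among them. T cell clusters were split by Cd8a and Cd8b1 against Cd4 and Foxp3, and fibroblasts and pericytes were merged. This scoring, and so which clusters have no name, was worked out with the data in view. Shares have exact Clopper-Pearson 95% intervals. Classes with at least 100 cells in both libraries were compared on counts summed per library and class, as CPM with exact Poisson intervals, and as log2 ratios with 5 CPM added, which understate the change of low genes. Intervals cover counting error only.

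No test of the condition was possible with 1 library per group. For each list the median log2 ratio of members with 20 or more UMIs over both libraries was taken, with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The lists were cytotoxic effector, exhaustion, naive and memory T, interferon-gamma response, type I interferon response, MHC class I, MHC class II, proliferation, inflammatory myeloid, immunosuppressive macrophage, chemokines and receptors, hypoxia and glycolysis, extracellular matrix, apoptosis and p53, unfolded protein response, dissociation stress, oxidative phosphorylation and phototransduction. T cell lists are reported in T cells, myeloid lists in macrophages, neutrophils and dendritic cells, and the others in the classes compared other than pooled T cells, which makes 87 values. This restriction was made after a first round of alternatives over 119 class and list pairs had been seen. In the same step an exact 0 stopped counting as a change of direction, and the CD8 T cell exhaustion list joined the main results; the closing section gives the numbers for both scopes.

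Named genes had at least 50 CPM in 1 library and 50 UMIs over both, a level of at least 0.25 of the gene's highest class in that library, and a difference of 1.5-fold or more. The 10 highest and 10 lowest log2 ratios were taken in all T cells, CD8 T cells, macrophages and tumour cells, and the 5 highest and 5 lowest in other classes. The rule fixed beforehand gave 10 to T cells and did not name CD8 T cells apart. That number was applied to CD8 T cells but not to CD4 and regulatory T cells. Receptor segments, mitochondrial, ribosomal, haemoglobin, predicted and sex-linked genes were left out. List members are named as examples. Some genes chosen this way are not reported here.

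On simulated counts with 200 changed genes, all genes changed 2.0-fold or 4.0-fold were called at the 1.5-fold limit in CD8 T cells and in tumour cells, as were 44.8% and 46.3% of those changed 1.5-fold. Of unchanged genes with a simulated level of at least 50 CPM, 0.567% of 3001 and 0.0% of 3206 were called. The simulation drew both libraries from the same profile with counting noise only. It held no difference in cells, clusters or free RNA between them, so these shares are not error rates of the real comparison.

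Alternatives fixed at the outset were a mitochondrial limit of 10%, a minimum of 1000 UMIs, doublets kept, Leiden resolutions 0.5 and 2, each library clustered alone, cells thinned to 2000 UMIs, other pseudocounts, other minimum counts for list members, per-cell means, centring on the median gene, and free RNA subtracted at 10% of the whole-library profile. Added after seeing the data were subtraction of the tumour profile at the share that Krt8 and Krt18 give, equal weights for tumour clusters and for macrophage clusters, cluster 14 counted as tumour, the cluster led by nuclear RNAs left out, and only members near their highest class. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.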

Results

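Single-cell RNA was sequenced from EMT6 tumours, which grow from a mouse mammary carcinoma cell line. The series concerns an mRNA vaccine in lipid nanoparticles against PDE6G, the inhibitory gamma subunit of the phosphodiesterase of rod photoreceptors. There were 2 libraries, 1 in each group, named Luc and PDE6G after their labels, and the labels give the same treatment text to both. The Luc library held 15497 barcodes with 93329535 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule), a median of 3909 per barcode. The PDE6G library held 11079 barcodes with 89067116 UMIs, a median of 7072. After filters and removal of called doublets, 14551 Luc cells and 10725 PDE6G cells were compared. With 1 library per group there was no replicate and no test of the condition: every interval is an exact 95% interval covering counting error only, and every difference is one between these 2 libraries. Paired values are given for Luc first and PDE6G second, and log2 ratios are PDE6G over Luc on the scale of CPM (UMIs of a gene scaled to the same total in every class) plus 5.

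The vaccine's target gene was examined first. Mouse Pde6g (ENSMUSG00000025386, chromosome 11: 120447605 to 120453500, minus strand, GRCm38) had 1 UMI in the Luc cells and 2 in the PDE6G cells, all in tumour cells. Among all barcodes it had 1 and 3 UMIs. Both libraries stood at or under the floor of 3 counts, which is 0.0352 CPM in Luc and 0.0354 CPM in PDE6G, so no fold is given and the gene does not check the labels. A human or recoded PDE6G sequence would not necessarily be counted under this gene. Of the 12 phototransduction genes listed, 3 had 20 or more UMIs over both libraries, with a median log2 ratio of -0.05.

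The cell classes answered which cells made up each tumour sample. CD8 T cells, the main killer lymphocytes, made up 20.8% of Luc cells (20.2 to 21.5) and 3.06% of PDE6G cells (2.74 to 3.40), a share 6.81-fold lower in PDE6G (6.07 to 7.65). Tumour cells, named by a list of epithelial markers that includes the keratins Krt8 and Krt18, took 29.7% (28.9 to 30.4) and 67.6% (66.7 to 68.5). These shares leave out clusters that scored highest for tumour markers but got no name, with 1598 Luc and 288 PDE6G cells. Neutrophils made up 11.2% (10.7 to 11.7) and 3.98% (3.62 to 4.37), and monocytes and macrophages 20.5% (19.9 to 21.2) and 14.1% (13.5 to 14.8). CD4 and regulatory T cells, which help or restrain the other lymphocytes, did not follow the CD8 T cells: their share was 2.23% (2.00 to 2.49) and 2.61% (2.32 to 2.93).

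**Figure D1:**
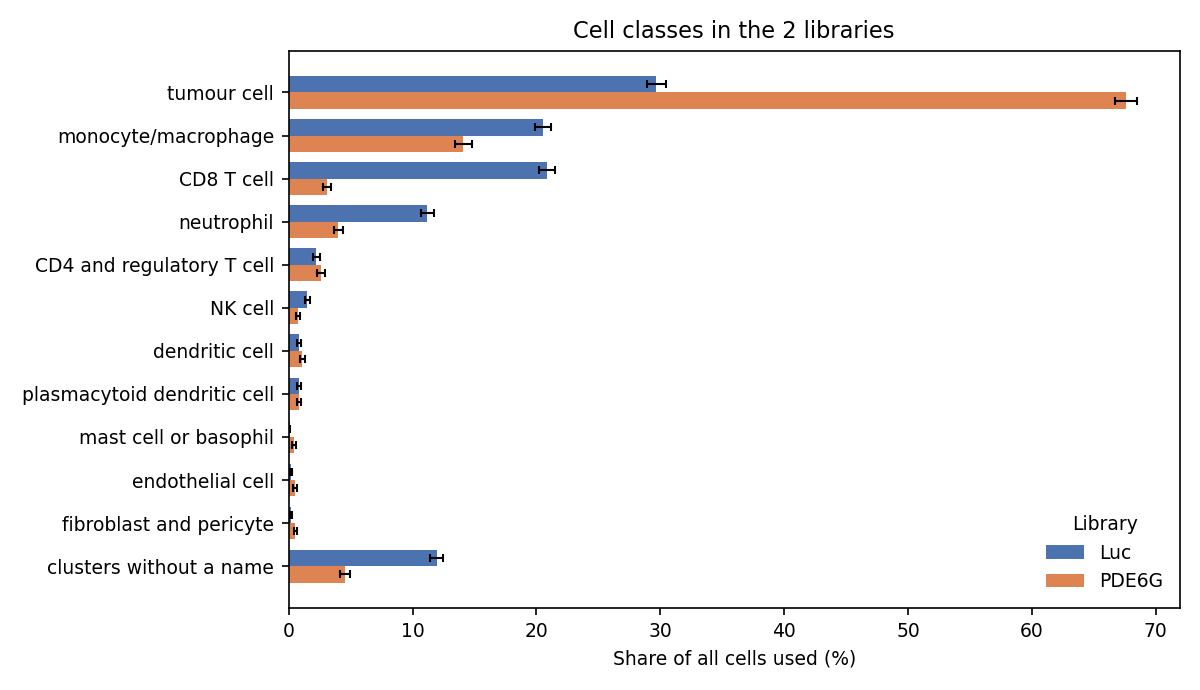
Share of all cells used (%) for each cell class, with 1 bar per library and exact binomial 95% intervals that cover counting error only. CD8 T cells stand at 20.8% in Luc and 3.06% in PDE6G, and tumour cells at 29.7% and 67.6%.

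Among the named immune cells alone, which were 58.0% of Luc and 26.8% of PDE6G cells, CD8 T cells were 35.9% (34.9 to 37.0) and 11.4% (10.3 to 12.6). CD4 and regulatory T cells were 3.85% and 9.75% of immune cells, macrophages 35.4% and 52.7%, neutrophils 19.3% and 14.9%, and dendritic cells 1.42% and 4.07%. Within T and NK cells together, CD8 T cells were 84.8% and 47.8%, CD4 and regulatory T cells 9.09% and 40.8%, and NK cells 6.13% and 11.4%. NK cells, innate killer lymphocytes, were 1.51% and 0.727% of all cells. Dendritic cells, which present antigen to T cells, were 0.825% and 1.09%, and plasmacytoid dendritic cells 0.797% and 0.793%. Mast cells or basophils were 11 and 44 cells (0.0756% and 0.410%), endothelial cells 30 and 55 (0.206% and 0.513%), and fibroblasts with pericytes 30 and 58 (0.206% and 0.541%).

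Clusters left without a name held 11.9% of Luc and 4.54% of PDE6G cells. They were cluster 5 (0.962% and 1.86%), cluster 11 (3.91% and 0.923%), cluster 14 (6.28% and 1.21%) and cluster 22 (0.790% and 0.550%). Cluster 14, led by Lbp and Dcn, scored highest for tumour markers but was kept out because its leading genes held fibroblast markers. Its Xist level (1.96 CPM) was near that of tumour cells (2.04 and 1.81 CPM) and far below that of fibroblasts and pericytes (241 and 341 CPM). That argues against fibroblasts as its cells. Counting it as tumour gave tumour shares of 35.95% and 68.8% and changed the log2 ratio of the tumour share from 1.19 to 0.94. The log2 ratio of the CD8 T cell share (-2.77) lay between -2.99 and -2.94 in 3 of the 4 other settings that set CD8 T cells apart, and at Leiden resolution 2 it stayed inside its counting interval. At resolution 0.5 and with thinned cells the class called CD8 held all T cells (-2.02 and -1.99). With each library clustered alone it was -1.80. There 224 of the 280 CD4 and regulatory T cells of PDE6G fell into a CD8 cluster, which accounts for a part of the move. PDE6G also had 691 T cells there, against 608. The log2 ratio of the CD4 and regulatory T cell share was then -2.18 instead of 0.23. Sorted by their own UMIs instead, T cells with Cd4 were 1.32% of Luc and 1.42% of PDE6G cells, those with Cd8a or Cd8b1 and without Cd4 were 17.3% and 2.14%, and those with neither were 4.45% and 2.12%.

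Inside the CD8 T cells, some effector and checkpoint transcripts were lower in PDE6G, while some interferon-gamma response and cell-cycle transcripts were higher. The chemokine Ccl5 (ENSMUSG00000035042, chromosome 11: 83525778 to 83530518, GRCm38), which draws T cells and monocytes, stood at 13720 CPM (13630 to 13820) and 5108 CPM (4934 to 5286). The granzyme genes Gzmf (71.5 and 11.0 CPM) and Gzmk (387 and 158 CPM), whose proteases are stored in cytotoxic granules, were also lower, as was the inhibitory receptor Tigit (237 and 127 CPM). The PDE6G value of Gzmf rests on few UMIs. Ccr7, a homing receptor for lymph nodes, stood at 143 and 354 CPM. The compared cells numbered 3030 with 5411879 UMIs and 328 with 637864 UMIs, mostly from cluster 8 in both libraries, at median depths of 1566 and 1662 UMIs. Cd8a or Cd8b1 was seen in 82.8% of them in Luc and 67.4% in PDE6G, and Cd4 in 1.22% and 4.27%. Ccr7 is a leading gene of the CD4 and regulatory T cell cluster, and Ccl5 and Gzmk of cluster 8. These values may therefore also carry a different makeup of the class, which was not tested.

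Of the 22 cytotoxic effector genes, 6 were at least 1.5-fold lower and 0 higher, and the list median was -0.17 (percentile 0.65 among 10000 matched random lists). Gzma was at 686 and 440.5 CPM. Klrg1, a receptor of terminal effector cells, was at 14.97 and 7.84 CPM, and its PDE6G value rests on few UMIs. The difference was not general: granzyme B gene Gzmb stood at 1550 and 1408 CPM, the perforin gene Prf1 at 160.4 and 152 CPM and Ifng at 157 and 179 CPM, each within 1.5-fold. The list median was 0.02 after tumour-cell RNA was subtracted and -0.48 with each cell weighted equally. It was -1.25 with each library clustered alone, where the class also held CD4 cells. Of 17 exhaustion genes, which mark chronically stimulated T cells, 5 were at least 1.5-fold lower and 0 higher (median -0.28, percentile 0.01). They included the checkpoint receptors Pdcd1 (574 and 347 CPM) and Ctla4 (414 and 246 CPM) and the regulator Tox (51.0 and 29.8 CPM). The 5 were counted without subtraction of tumour-cell RNA. That subtraction took the log2 ratio of Tigit, also among the 5, from -0.87 to -0.71. It left the list median inside its counting interval (-0.44 to -0.08). Whether Pdcd1, Ctla4 and Tox stay past 1.5-fold after it is not reported here. The exhaustion median was -0.48 with each cell weighted equally, -1.08 clustered alone and -0.12 over members near their highest class. The 14 naive and memory genes were split, with 3 higher and 2 lower (median -0.11), the quiescence factor Klf2 standing at 553 and 307 CPM.

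Of 20 measured interferon-gamma response genes in CD8 T cells, 10 were at least 1.5-fold higher and 0 lower (median 0.58, percentile 100). The median was 0.41 over the 13 members near their highest class, and 0.21 when each library was clustered alone, where the class also held CD4 cells. The guanylate-binding protein gene Gbp2 was at 125 and 227 CPM and the chemokine gene Cxcl10 at 73.7 and 174 CPM. Of 23 measured proliferation genes, 12 were higher and 0 lower (median 0.63, percentile 100), among them Mki67 (104 and 185 CPM) and Mcm2 (44.7 and 90.9 CPM), which serves DNA replication. All 17 measured matrix genes were higher (median 1.38), including Col3a1 (3.70 and 42.3 CPM) and Sparc (27.9 and 105 CPM). The hypoxia and glycolysis list had 5 of 19 members higher (median 0.40), and its median was 0.13 after tumour-cell RNA was subtracted. The tumour keratins Krt8 and Krt18 stood in CD8 T cells at 4.96% of their tumour-cell level in Luc and 16.6% in PDE6G.

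The genes ranked highest in PDE6G CD8 T cells by the size rule were Penk, which encodes the opioid precursor proenkephalin (8.69 and 104 CPM), and Areg, an EGF receptor ligand (26.8 and 114 CPM). They were followed by Nup155 of the nuclear pore (13.3 and 54.9 CPM), the histone genes H3c6 (27.9 and 95.6 CPM) and H4c4 (59.1 and 162 CPM), the interferon-inducible Ifi202b (14.2 and 53.3 CPM), the ferroxidase gene Cp (29.0 and 94.1 CPM), the fatty acid desaturase gene Scd2 (30.5 and 95.6 CPM), the unconventional myosin gene Myo10 (21.6 and 65.8 CPM) and the protease inhibitor gene Timp2 (43.6 and 119 CPM). Besides Gzmf, Ccl5, Gzmk and Tigit, the lowest were the heat-shock gene Hspa1a (60.2 and 28.2 CPM), Isca1 of iron-sulfur cluster assembly (65.0 and 31.4 CPM), Cript (87.2 and 43.9 CPM), the T cell surface receptor gene Cd5 (201 and 107 CPM), Ocel1 (64.7 and 32.9 CPM) and the signalling adaptor gene Sh2d1a (80.4 and 42.3 CPM). With each cell weighted equally, the log2 ratio of Penk was 1.88 instead of 2.99. The other CD8 T cell list medians were type I interferon response 0.09, MHC class I -0.09, MHC class II 0.34, chemokines and receptors 0.16, apoptosis and p53 -0.06, unfolded protein response 0.07, dissociation stress 0.03 and oxidative phosphorylation -0.08. The median of all measured genes was itself 0.11 in this class, 0.12 in all T cells, 0.12 in macrophages and 0.12 in dendritic cells.

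All T cells pooled (3355 and 608 cells) had a different makeup in the libraries, with 3030 and 328 CD8 T cells among them, so their values also carry that makeup. Il13, a type 2 cytokine gene, stood at 5.31 and 59.2 CPM and Cd4 at 54.6 and 237 CPM. Other genes higher in PDE6G were Penk, Areg, Iigp1, Ifngr2, Itgae, Rln3, Sdc4 and Prdx4, with log2 ratios from 1.74 to 2.17. Lower were Gzmf, Ccl5, Gzmk, Osgin1, the granule protein gene Nkg7 (2102 and 933 CPM), Sh2d1a, Cst7, Cd8b1 (935 and 434 CPM), Pdcd1 (542 and 256 CPM) and Dusp2. The list medians were -0.71 for cytotoxic effector, -0.43 for exhaustion and 0.35 for naive and memory genes. The last was -0.28 when each library was clustered alone.

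CD4 and regulatory T cells (325 and 280 cells) had less of the cytokine transcripts Csf2 (320.4 and 66.0 CPM), encoding the myeloid growth factor GM-CSF, and Ifng (65.4 and 24.96 CPM) in PDE6G. Among the 5 highest genes were Ccnd1, a cyclin of G1 phase, at 45.8 and 348 CPM, and Ube2c, of mitotic exit, at 8.17 and 83.8 CPM. The histone genes H3c6 (18.0 and 90.9 CPM) and H1f5 (44.1 and 193 CPM) and the lipid gene Scd2 (27.8 and 114 CPM) completed the 5 highest, and Ecm1 (389 and 149.8 CPM), Krt83 (129 and 51.7 CPM) and the glutathione synthesis gene Gclc (63.8 and 24.96 CPM) the 5 lowest. The proliferation median was 0.49 with 5 of 17 members higher, and it was -0.32 when cells under 1000 UMIs were left out.

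Of the naive and memory list, 4 genes were lower and 2 higher in CD4 and regulatory T cells (median -0.43). Its lower members included Klf2 (930 and 556 CPM) and the survival gene Bcl2 (214 and 120 CPM). The cytotoxic list had a median of -0.41 with 4 of 13 members lower, and the exhaustion list -0.20 with 3 of 13 lower. Other medians were interferon-gamma response 0.22, type I interferon response -0.02, MHC class I -0.08, MHC class II 0.00, chemokines and receptors -0.34, apoptosis and p53 -0.11, unfolded protein response 0.11, dissociation stress -0.04 and oxidative phosphorylation -0.03. The hypoxia median was 0.23, and -0.10 with members of 100 or more UMIs. The matrix median was 1.81, with Krt8 and Krt18 at 4.11% and 17.1% of the tumour level in this class.

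T cell receptor V segments, which the 5' chemistry reads, showed a different leading Trbv segment in CD8 T cells of each library. Trbv1 made up 18.7% of Trbv UMIs in Luc (17.7 to 19.7) and 5.22% in PDE6G (3.50 to 7.46). Trbv29 made up 6.67% (6.05 to 7.33) and 17.4% (14.2 to 20.8), and Trbv19 8.73% and 17.2%. Usage was of similar evenness, with an inverse Simpson index of 10.9 over 5956 UMIs and 9.38 over 536 UMIs. UMIs of a cell or clone are not independent, so these intervals are too narrow. With cells thinned to 1000 UMIs, which left out 468 and 59 shallower cells, Trbv1 was seen in 18.0% and 4.97% of cells with a Trbv UMI, and the last share rests on 7 cells. Among Trav segments the most used was Trav7-4 in Luc (12.7%) and Trav3-3 in PDE6G (17.4%). In CD4 and regulatory T cells Trbv1 led in both libraries, at 16.9% and 21.3%.

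**Figure D2:**
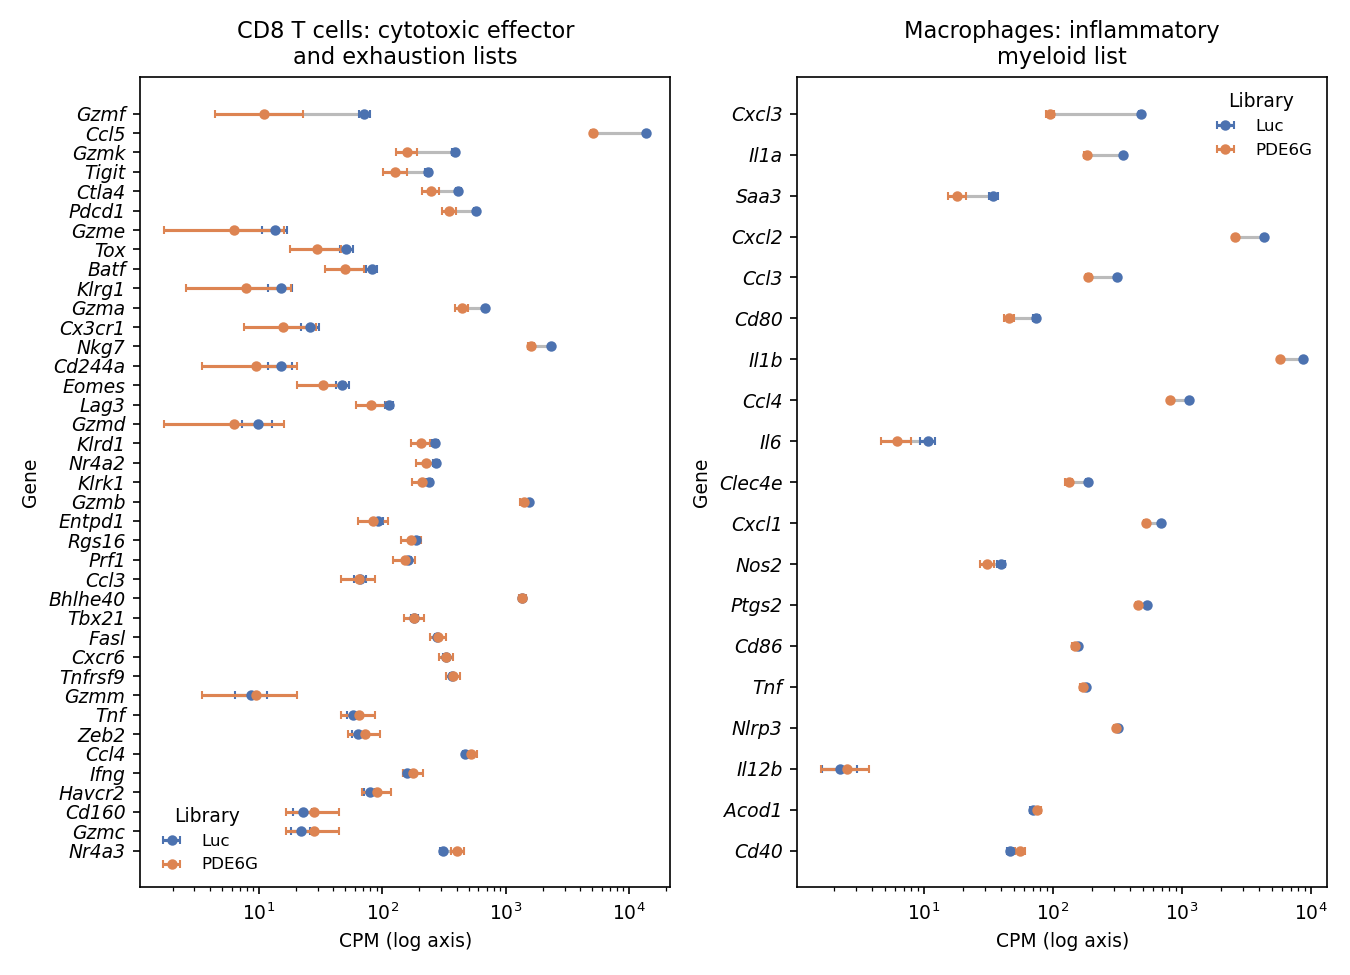
CPM on a log axis in Luc and PDE6G for the cytotoxic effector and exhaustion lists in CD8 T cells (left) and the inflammatory list in macrophages (right), with exact Poisson 95% intervals that cover counting error only. Ccl5 in CD8 T cells stands at 13720 and 5108 CPM, and Cxcl3 in macrophages at 479.8 and 95.3 CPM.

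Monocytes and macrophages (2986 and 1513 cells, median depths of 5470 and 5377 UMIs) had less of the inflammatory transcripts in PDE6G, in part because their clusters were mixed differently. Of 19 measured inflammatory myeloid genes, 7 were at least 1.5-fold lower and 0 higher (median -0.49, percentile 0.0). Cluster 1, led by genes such as Ccl24, F10, Plac8, Arg1 and Cxcl3, held 41.1% of Luc and 26.0% of PDE6G macrophages, and cluster 0, led by C1q genes, the rest. Within cluster 0, 3 members were lower and 1 higher (median -0.16), within cluster 1, 7 of 18 were lower and 0 higher (median -0.33), and with both weighted equally 5 were lower (median -0.27). Dissociation stress genes, which tissue digestion can induce, were also lower in macrophages (median -0.26, percentile 0.0, 2 of 18 past 1.5-fold). The neutrophil attractant Cxcl3 stood at 479.8 and 95.3 CPM, Cxcl2 at 4322 and 2590 CPM, and the cytokine genes Il1b at 8719 CPM (8677 to 8762) and 5790 CPM (5740 to 5839) and Il1a at 350 and 184 CPM. With equal weights the log2 ratios of Il1b (-0.45) and Cxcl2 (-0.54) no longer passed 1.5-fold. The eosinophil attractant Ccl24 (553 and 157 CPM) and the metalloprotease gene Adamdec1 (88.6 and 21.8 CPM) were the lowest of the named genes. Cxcl3 had a lower log2 ratio (-2.27) but was not named, as its Luc level here was under 0.25 of that in its highest class. The neutrophil gene S100a8 stood in macrophages at 143 and 23.1 CPM, which is 0.828% and 0.239% of its neutrophil level. A part of neutrophil RNA in the macrophage values was not tested.

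Also named as lower in macrophages were the heat-shock genes Hspa1a (116 and 51.7 CPM) and Hspa1b (86.9 and 38.5 CPM), the cell-cycle regulator Rgcc (114 and 51.9 CPM), the monocyte gene Plac8 (556 and 272 CPM), the ubiquitin ligase gene Fbxo32 (103 and 49.1 CPM), coagulation factor gene F10 (154 and 74.6 CPM) and the adhesion receptor gene Adgre5 (192 and 99.1 CPM). Genes higher in PDE6G included Fcrls (9.48 and 50.8 CPM) and Tmem119 (23.1 and 55.0 CPM), both known from microglia, the fatty acid synthesis gene Fasn (30.4 and 67.9 CPM), and the monocyte attractant Ccl12 (292.5 and 602 CPM). H4c4, Mcm6, H1f5, Top2a and Atad2, which serve chromatin and DNA replication, were higher by log2 ratios of 0.79 to 1.08. The histone genes among them were not particular to macrophages. The log2 ratio of H4c4 was 1.38 in CD8 T cells and 3.045 in neutrophils. That of H1f5 was 2.01 in CD4 and regulatory T cells and 2.57 in neutrophils. With both clusters weighted equally, 8 of the 10 lower and 8 of the 10 higher genes named for this class stayed past 1.5-fold, and Ccl12 had log2 ratios of 1.01 in cluster 0 and -0.69 in cluster 1.

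The immunosuppressive macrophage list moved both ways, with 3 members higher and 4 lower of 21 (median -0.10). Arg1, which depletes arginine, stood at 1422 and 802 CPM and Apoe at 12510 and 8178 CPM, whereas the scavenger receptor gene Cd163 stood at 0.646 and 20.2 CPM and Folr2, a folate receptor of tissue macrophages, at 13.0 and 28.9 CPM. Cxcl13, a B cell attractant, had 0 UMIs in Luc and 82 in PDE6G macrophages. Proliferation genes had a median of 0.53, with 10 of 24 higher and 0 lower, such as Mki67 (74.6 and 128 CPM). The interferon-gamma list had a median of 0.22, with Cxcl10 at 164 and 272 CPM, and the type I interferon list -0.19. The matrix list had 12 of 20 genes higher (median 0.72), while Krt8 and Krt18 stood at 1.60% and 7.28% of the tumour level. Other medians were MHC class I 0.02, MHC class II -0.18, chemokines and receptors -0.01, hypoxia -0.13, apoptosis and p53 -0.05, unfolded protein response 0.04 and oxidative phosphorylation 0.07.

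The lowest named genes in neutrophils of PDE6G (1629 and 427 cells) included Ngp, Camp and Ltf, which immature neutrophils express for their secondary granules, though no list of such genes was tested. Ngp stood at 2862 and 95.8 CPM, the cathelicidin gene Camp at 951 and 43.7 CPM, and the lactoferrin gene Ltf at 1189 and 67.2 CPM, with Ifitm6 (458 and 68.9 CPM) and Chil3 (63.9 and 6.72 CPM) also lower. With each cell weighted equally the log2 ratios were smaller: -2.95 instead of -4.05 for Ltf and -0.82 instead of -2.56 for Chil3. The PDE6G value of Chil3 rests on few UMIs. The highest genes were the histone genes H4c4 (16.2 and 169.8 CPM), H3c6 and H1f5, the protease gene Htra1 (13.4 and 104 CPM) and Oaf (14.6 and 113 CPM), and the log2 ratio of Oaf was 0.00 after tumour-cell RNA was subtracted.

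Interferon-gamma response genes in neutrophils had a median of 0.46, with 7 of 20 higher and 1 lower, but the median was 0.02 when each library was clustered alone, with 1133 Luc cells in the class instead of 1629. Gbp2 stood at 764 and 1187 CPM and Cd274, encoding the checkpoint ligand PD-L1, at 807 and 1175 CPM, while Nos2 stood at 133 and 63.9 CPM. The MHC class I median was 0.51 and that of MHC class II 0.44. The type I interferon median was 0.44, and -0.07 when each library was clustered alone. Krt8 and Krt18 stood in neutrophils at 6.69% and 26.9% of the tumour level, and subtraction of tumour-cell RNA took the proliferation median from 0.89 to -0.10. Medians were also -0.24 for inflammatory myeloid, 0.40 for immunosuppressive macrophage (-0.10 when clustered alone), 0.47 for chemokines and receptors, -0.16 for hypoxia, 1.39 for matrix, -0.34 for apoptosis and p53, 0.10 for unfolded protein response, -0.21 for dissociation stress and 0.20 for oxidative phosphorylation genes.

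In dendritic cells (120 and 117 cells) none of the 10 MHC class II genes, which encode the molecules that show antigen to CD4 T cells, differed by 1.5-fold. Their median log2 ratio was -0.51 (percentile 0.04), -0.33 after tumour-cell RNA was subtracted and -1.10 when each library was clustered alone, where 372 PDE6G cells took that name, with H2-Aa at 13050 and 8811 CPM and the activator Ciita at 128 and 151 CPM. The chemokine gene Ccl22, typical of migrating dendritic cells, was at 93.5 and 279 CPM, and Xcr1, of the cross-presenting kind, at 192 and 114 CPM. The 5 highest genes were the integrin gene Itgb4 (5.27 and 85.5 CPM), Clu (29.0 and 171 CPM), Hhip (15.8 and 101 CPM), the fibronectin gene Fn1 (227 and 1153 CPM) and Maged1 (19.8 and 116 CPM). The 5 lowest were Sult1a1 (124 and 28.0 CPM), Qpct (154 and 39.2 CPM), Slc16a6 (132 and 36.4 CPM), the interferon-inducible Usp18 (77.7 and 25.2 CPM) and Pias1 (63.2 and 21.0 CPM). Krt8 and Krt18 stood at 1.82% and 13.8% of the tumour level, beside a matrix median of 1.18. The immunosuppressive macrophage median was -0.38, but 0.36 with each cell weighted equally and 0.77 when each library was clustered alone. Other medians were interferon-gamma response 0.07, type I interferon response -0.11, MHC class I -0.06, proliferation -0.12, inflammatory myeloid -0.13, chemokines and receptors 0.09, hypoxia 0.08, apoptosis and p53 0.04, unfolded protein response -0.05, dissociation stress -0.06 and oxidative phosphorylation -0.01.

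In tumour cells, MHC class II genes were much lower in PDE6G. Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18: 60803848 to 60812652, GRCm38), stood at 1921 CPM (1908 to 1934) and 788 CPM (782 to 795). H2-Aa was at 692.5 and 232 CPM, H2-Ab1 at 427 and 147 CPM and H2-Eb1 at 494 and 159 CPM. Of 10 class II genes, 7 were at least 1.5-fold lower and 0 higher (median -1.28, percentile 0.0), and Ciita, their transcriptional activator, was at 10.8 and 6.86 CPM. The tumour class held 4317 and 7253 cells with median depths of 9552 and 8883 UMIs. Luc tumour cells came mainly from clusters 7 (25.6%) and 6 (22.03%), and PDE6G tumour cells mainly from clusters 13 (29.5%) and 7 (18.6%).

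Each of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 was lower in PDE6G in 8 of 8 tumour clusters, and at least 1.5-fold lower in 7. Cd74 was seen in 92.4% of Luc and 77.2% of PDE6G tumour cells. In CD8 T cells, which should largely lack it, the shares were 46.4% and 59.8% at median depths of 1566 and 1662 UMIs, higher rather than lower in PDE6G. MHC class I genes had a median of -0.28 with 1 of 19 at least 1.5-fold lower, H2-Q7 (97.54 and 61.7 CPM).

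**Figure D3:**
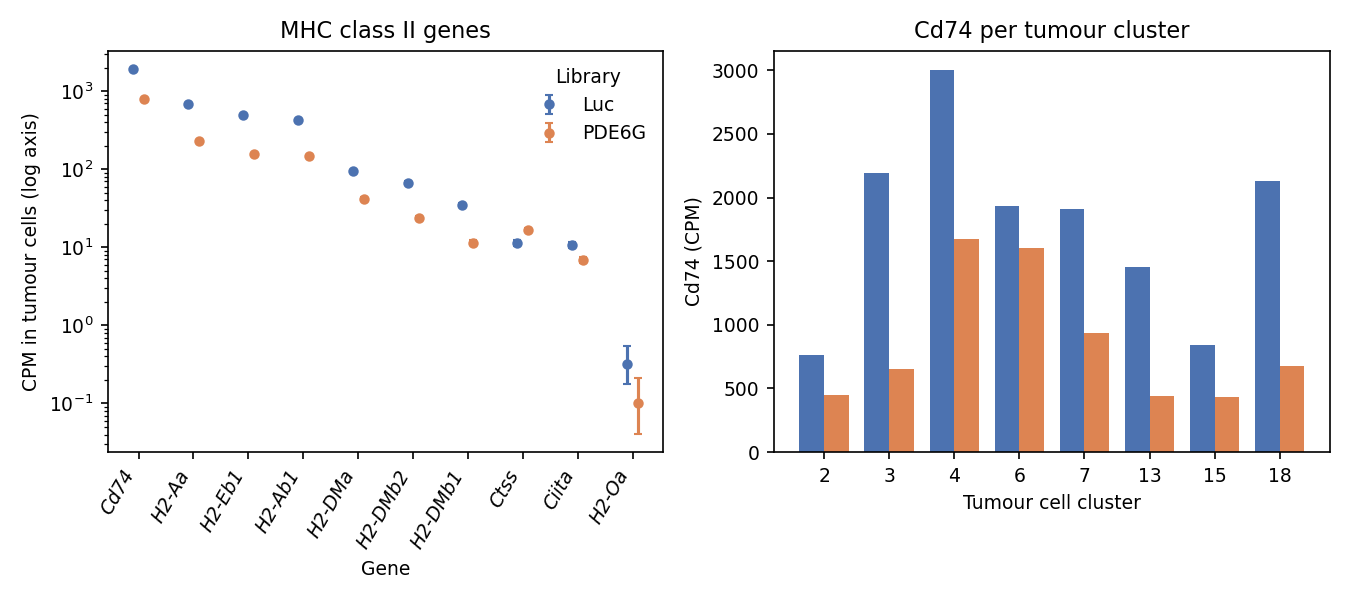
Left, MHC class II genes in tumour cells as CPM on a log axis for Luc and PDE6G, with exact Poisson 95% intervals that cover counting error only. Right, Cd74 in CPM for each tumour cluster, lower in PDE6G in 8 of 8 clusters.

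The sterol pathway genes Idi1 (20.1 and 55.5 CPM), Sqle (35.3 and 83.8 CPM) and Cyp51 (28.8 and 68.3 CPM) were among the named genes higher in PDE6G tumour cells, and no list of that pathway was tested. Others included Pthlh, a parathyroid hormone-like factor (46.8 and 107 CPM), the stromelysin gene Mmp3 (82.7 and 178 CPM), the zinc transporter gene Slc39a10 (25.2 and 55.6 CPM), Areg (125 and 247 CPM), the TGF-beta receptor gene Tgfbr2 (77.2 and 151 CPM) and the ephrin receptor gene Epha1 (39.8 and 79.4 CPM). Lower genes included the transcription factor genes Klf9 (66.0 and 21.1 CPM), Foxo1 (109 and 57.2 CPM) and Xbp1 (139 and 77.1 CPM), Mtarc2 (371 and 155 CPM), Rflnb (90.7 and 39.3 CPM), the amino acid transporter gene Slc43a2 (52.1 and 26.4 CPM), the death receptor gene Tnfrsf21 (77.0 and 41.1 CPM), the cytoskeletal gene Add3 (51.4 and 27.6 CPM) and Mgp, matrix Gla protein (473 and 272 CPM). Pthlh and Mmp3 lead cluster 13 and Mtarc2 leads cluster 6, so their values are not independent of the different cluster makeup of the libraries.

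Proliferation genes had a median of 0.35 in tumour cells, with 4 of 24 higher and 0 lower, including Mki67 (124 and 232 CPM) and Rrm2 (37.2 and 64.8 CPM). That median was -0.04 when cells under 1000 UMIs were left out, a setting in which more cells of tumour-like clusters had no name. Hypoxia and glycolysis genes had a median of 0.31, with Car9, a hypoxia-induced carbonic anhydrase gene, at 71.1 and 121 CPM. The interferon-gamma response median was -0.07, with members from -0.75 for Psmb9 to 0.29 for Cxcl10, and the type I interferon median was -0.25. The monocyte attractant Ccl2 stood at 49.5 and 94.9 CPM, in a chemokine list with a median of 0.03. The matrix median was 0.21, with Col3a1 at 0.464 and 7.84 CPM. Other medians were apoptosis and p53 -0.05, unfolded protein response -0.08, dissociation stress -0.12 (0.01 at Leiden resolution 0.5) and oxidative phosphorylation 0.02.

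**Figure D4:**
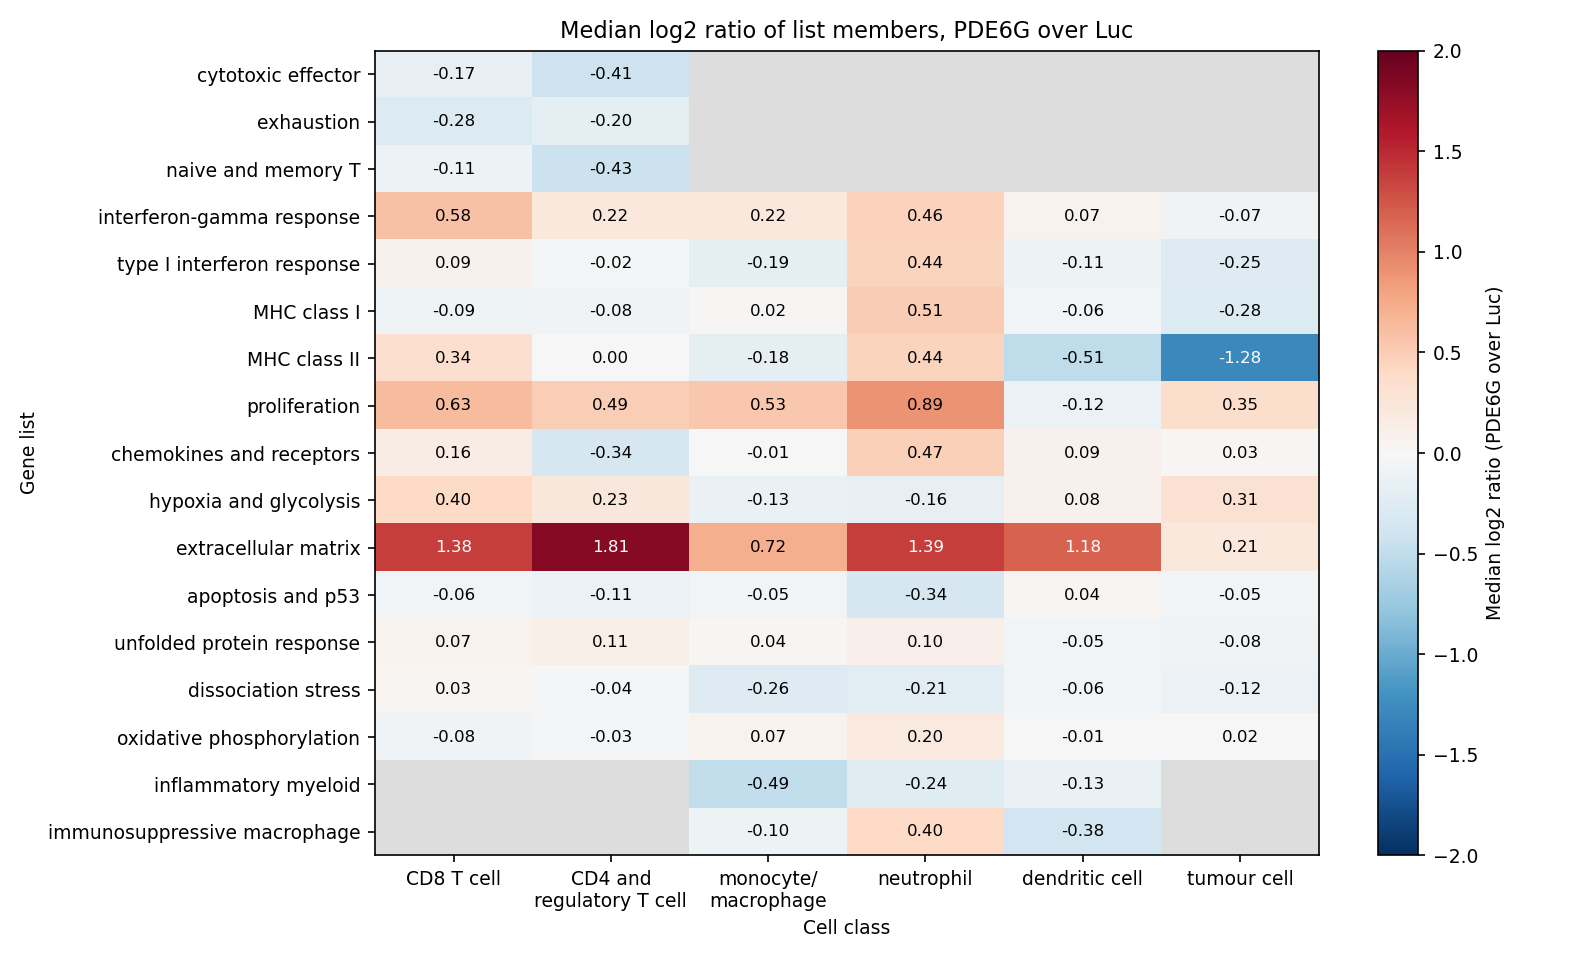
Median log2 ratio (PDE6G over Luc) of the measured members of each gene list in each compared class, with grey where a list was not reported for a class. The tumour class has its lowest value for MHC class II (-1.28), and the 5 immune classes have matrix medians from 0.72 to 1.81.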

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

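Alternatives chosen only after the data were seen were the tumour-RNA subtraction, equal weights for tumour clusters, the cluster led by Lbp and Dcn counted as tumour, the cluster led by nuclear RNAs left out, equal weights for macrophage clusters, and only members near their highest class; the others were planned. A change of direction is a change of sign of a called value, one whose counting interval excludes 0 and, for lists, that also lies outside the central 95% of matched random lists. Over 87 list medians, 1044 of 1316 values under alternatives stayed inside the counting interval, 261 moved beyond it and 11 changed direction. Called or not, 1207 of the 1316 kept their sign, and 40 of the 87 medians kept it in every setting. Over 110 named genes, 348 of 420 stayed inside it and 0 changed direction, with 419 keeping their sign. Over 15 shares, 68 of 100 values stayed inside it, 30 moved and 2 changed direction, with 95 keeping their sign and 11 of the 15 keeping it in every setting. The named genes were recomputed only with another pseudocount, centring, per-cell means and, outside tumour cells, tumour-RNA subtraction. A changed pseudocount cannot change a sign, and these genes were chosen for large ratios. No filter or clustering was changed for them, so their count cannot be set against those of lists and shares. These list counts come from a second round: the first covered 119 class and list pairs, and with a value of exactly 0 counted it gave 19 changes of direction among lists against 11 among the 87, and it was narrowed after those were seen. Of the 8 left out, 6 concern inflammatory myeloid genes in tumour cells. The pseudobulk depth limits small classes: 117 dendritic cells and 280 CD4 and regulatory T cells in PDE6G. No paired analysis was possible because there is 1 library per group. Leiden resolution 0.5 and thinning gave no CD4 and regulatory T cell class and so no value for it, and their class called CD8 held all T cells (3358 and 610 cells, and 923 and 229), so these settings do not measure CD8 T cells alone. Clustered alone, the CD8 class took in 224 of 280 CD4 and regulatory T cells of PDE6G and 14 of 325 of Luc.

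Log2 ratios of CD8 T cells among all cells (main value -2.77) were -2.02 at resolution 0.5, -2.94 with doublets kept, -1.99 thinned, -1.80 with each library clustered alone, -2.96 with at least 1000 UMIs and -2.99 with the mitochondrial limit of 10%. Among immune cells (-1.65) they were -0.97 at resolution 0.5, -0.85 thinned, -0.94 clustered alone, -1.84 with 1000 UMIs and -1.93 with the limit of 10%. Macrophages (-0.54) gave -0.44 at resolution 0.5, -0.44 at resolution 2, -0.65 with doublets, -0.94 thinned and -0.44 with the limit of 10%. Neutrophils (-1.49) gave -2.66 thinned and -0.91 clustered alone. Tumour cells (1.19) gave 1.31 at resolution 0.5, 0.87 thinned, 0.94 with the Lbp and Dcn cluster, 1.39 clustered alone, 1.64 with 1000 UMIs and 1.101 with the limit of 10%. Clustered alone, where 635 PDE6G cells were CD8 and 56 CD4, the CD4 and regulatory T cell share was -1.32 of immune cells (1.34) and -2.18 of all cells (0.23). The dendritic cell share (0.40) was -0.15 thinned and 2.06 clustered alone, where 372 PDE6G cells took that name instead of 117.

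In CD8 T cells the cytotoxic median (-0.17) was -0.71 at resolution 0.5, where it is a value of all T cells, -1.25 clustered alone, -0.48 by per-cell mean and 0.0154 with tumour RNA subtracted; exhaustion (-0.28) was -1.08 clustered alone and -0.48 by per-cell mean. The macrophage inflammatory median (-0.49) was -0.61 when centred, -0.27 with equal weights for both clusters and -0.36 with members near their highest class. Tumour MHC class II (-1.28) was -1.40 at resolution 0.5, -1.13 with equal weights, -1.37 clustered alone, -1.33 with free RNA subtracted, -1.12 by per-cell mean, -1.46 with 1000 UMIs, and -1.37 and -0.95 with pseudocounts of 1 and 20. MHC class I (-0.28) was -0.33 at resolution 0.5, -0.19 with the Lbp and Dcn cluster, -0.22 with equal weights, -0.34 clustered alone, -0.19 by per-cell mean, -0.38 with 1000 UMIs, -0.24 with the limit of 10% and -0.24 with members near their highest class. Tumour proliferation (0.35) was 0.27 at resolution 0.5, 0.56 with the Lbp and Dcn cluster, 0.11 with equal weights, 0.19 clustered alone, 0.45 by per-cell mean, 0.45 with the limit of 10%, 0.40 and 0.27 with pseudocounts of 1 and 20, and -0.0357 with 1000 UMIs, which left 2898 Luc and 1474 PDE6G cells of tumour-like clusters without a name, against 1598 and 288. Trbv29 in Luc was 6.67% of Trbv UMIs and was seen in 5.60% of thinned cells with a Trbv UMI, which is another measure.

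Other changes of direction were naive and memory T in all T cells (-0.28 from 0.35), type I interferon response (-0.0669 from 0.44) and immunosuppressive macrophage genes (-0.10 from 0.40) in neutrophils, and immunosuppressive macrophage genes in dendritic cells (0.77 from -0.38), all clustered alone; the last also by per-cell mean (0.36). Clustered alone, the neutrophil interferon-gamma response median (0.46) kept its sign but was 0.0238, that of CD8 T cells (0.58) was 0.21, and dendritic cell MHC class II (-0.51) was -1.10. Proliferation in CD4 and regulatory T cells was -0.32 with 1000 UMIs (0.49), hypoxia there -0.10 with members of 100 UMIs (0.23), neutrophil proliferation -0.10 with tumour RNA subtracted (0.89), and tumour dissociation stress 0.0110 at resolution 0.5 (-0.12). Beyond the cluster makeup given here, the cause was not tested.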

Other observations

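The tests of dilution, of recovery, of exchanged labels, of collagen genes, of outside RNA shared by immune classes and of all 3 explanations for MHC class II were chosen only after the result was seen; the tests by tumour-RNA subtraction and for doublets were chosen after other data were seen but before their own results. Fibroblasts and pericytes, too few to compare by the rule, kept high collagen levels in both libraries: Col1a1 stood at 18970 CPM in 30 Luc cells and 15060 CPM in 58 PDE6G cells, and Col3a1 at 14230 and 11570 CPM. Endothelial cells held Krt8 and Krt18 at 21.2% and 54.5% of the tumour level, and plasmacytoid dendritic cells at 8.23% and 26.7%.

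CD8 T cells were a lower share of PDE6G cells. Their share of immune cells alone had a PDE6G over Luc ratio of 0.318 (0.283 to 0.357), which argues against dilution by tumour cells as the whole cause. Poor recovery of cells with few UMIs should have lowered CD4 and regulatory T cells too, which have similar depth, but their ratio was 1.17 (0.993 to 1.38). That class depends on joint clustering: with each library clustered alone it was 2.37% of Luc and 0.522% of PDE6G cells, as 224 of its 280 PDE6G cells fell into a CD8 cluster. T cells sorted by their own UMIs do not depend on that split, and those with Cd4 had a ratio of 1.07 (0.862 to 1.34), or 1.15 (0.923 to 1.42) among the T cells of the separate clusterings, against 0.123 (0.107 to 0.142) for those with Cd8a or Cd8b1 and without Cd4. As background, Cd4 was seen in 0.0% of Luc and 0.468% of PDE6G neutrophils, and T cells with neither had a ratio of 0.475 (0.407 to 0.554). Such a loss is therefore not the whole cause, but neutrophils (ratio 0.356) and NK cells (0.483), which also have few UMIs, were lower too, so a part of it stays open. Exchanged labels cannot be told apart from correct ones, since Pde6g had 2 UMIs in PDE6G and 1 in Luc. An effect of the immunization, or of tumour size or time, which were not used here, stays open and untested with 1 library per group.

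Matrix genes were higher in CD8 T cells of PDE6G. Doublets with tumour cells would pile keratin UMIs into a few cells. The top 5% of PDE6G CD8 T cells held 0.889 times the keratin share expected by depth. In Luc the top 5% held 39.2%, above the 32.7% to 37.1% expected by depth. A doublet's own depth raises its expected share, so the test is weak against deep doublets. Scrublet called fewer doublets than the expected rate: 6.01% against 12.4% in Luc and 3.20% against 8.86% in PDE6G. Cluster 22, without a name and outside the CD8 T cells, had the highest doublet score of the 24 clusters (0.194). T cell genes such as Cd3g and Lat led it beside Lbp, with Krt18 at 1457 CPM. Unremoved doublets of T and tumour cells therefore stay open as a source. Tumour RNA in the droplets was not told apart from another source for the list as a whole. The list median stayed at 1.25 after subtraction, above the limit of 0.58 set beforehand. A counting interval of 0.507 to 1.28 reaches that limit, but it was scaled to the totals before subtraction and the median to those after. That interval therefore lies too low for the median and cannot decide the question. Col1a1, Col1a2 and Col3a1 summed to 4.0 times (2.96 to 5.29) their tumour-cell level, which tumour RNA would not give. RNA from outside the cells, shared by all immune classes, may account for it, as the lowest matrix median among the 5 compared immune classes was 0.72, in macrophages. Subtracting the average RNA of the whole library at the keratin share, computed afterwards, left 1.00 in CD8 T cells, 1.02 in neutrophils and 0.67 in CD4 and regulatory T cells, but 0.15 in macrophages and -0.33 in dendritic cells, so an average of the library accounts for it only in part and another outside profile was not tested.

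MHC class II genes were lower in PDE6G tumour cells. Free RNA of macrophages would bring their other transcripts, but C1qa, C1qb, C1qc, Lyz2 and Apoe stood at a median of 0.293% of their macrophage level in Luc tumour cells against 11.9% for class II genes, a ratio of 0.0246. Different clusters do not account for it, as the median with equal cluster weights was -1.13. A general fall of interferon-gamma signalling of that size is not seen at harvest, since that list's median was -0.0745 in tumour cells. Its members ran from -0.75 for Psmb9 to 0.29 for Cxcl10, and earlier signalling was not measured. A smaller fall is not excluded, as the median was below 0 in 17 of 17 alternatives (-0.25 to -0.03). Ciita was also lower (10.8 and 6.86 CPM). A difference tied to the groups is therefore a hypothesis from the same data, and with 1 library per group it may equally be a difference between 2 tumour samples.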
